A study of Oryza sativa with 44 samples.

How the data were processed

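The data are RNA-seq libraries of rice leaves (Oryza sativa, indica cultivar Pusa Basmati 1), 44 libraries in 22 groups of 2. Per the labels, total RNA was extracted from leaves or leaf strips of plants aged 6 weeks, and libraries were made with a directional kit. Groups were taken from the sample titles. The titles mark 1 of the 2 libraries of each group as replicate, without saying that the mark stands for a shared plant, batch or day. No label says that both libraries of a group came from separate plants, so p-values measure only the spread between these libraries, which may be technical.

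The deposited values are FPKM (fragments mapped to a gene, relative to transcript length and to the library's mapped fragments) per gene record, with a 95% interval, per the file headers. Trimmomatic, HISAT2 and Cufflinks 2.2.1 are named in the submitters' processing notes, with no role or order. Genome build, annotation, mapping settings and strand setting are not given in the sources used here. Each library has its own table, in which annotated gene IDs stand beside loci assembled from that library, numbered separately in each table. FPKM is relative to each library's own total, so a few abundant transcripts that change move all other values. Reads shared by close paralogs, such as the neighbouring genes JAZ9, JAZ10 and JAZ11 or WRKY62 and WRKY76, may have been split by the authors' software, and their separate values are uncertain. The same holds for overlapping genes.

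Records were joined across libraries by annotated gene ID or, where a library held only an assembled record, by position, with an overlap of at least 0.8 of the joint span and a span of at least 200 bp. The join gave 26544 annotated genes, 20429 of them valued in all 44 libraries, and 27352 assembled loci without an ID, 5704 of them valued in all 44. Starts in the deposited tables count from 0 and are printed here counted from 1. The libraries form 3 experiments, a wound course (6 groups, 12 libraries), a peptide course (9 groups, 18 libraries) and a genotype experiment (7 groups, 14 libraries). Each was processed apart, because leaf strips and leaves differ and no library is shared. FPKM was divided per library by the median ratio to the geometric mean library of its experiment ("scaled FPKM" in the text). Genes were tested if valued in every library of the experiment and at 1 FPKM or more in at least 2 of them. This left 13488 genes in the wound course, 14142 in the peptide course and 14447 in the genotype experiment.

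Differences were tested with limma 3.58.1 in R 4.3.3 on log2(scaled FPKM + 1), with group means fitted per experiment, empirical Bayes moderation with a trend and robust settings, and Benjamini-Hochberg adjustment over the genes tested in a comparison. A gene rose or fell where the adjusted p was below 0.05 and the fold change was at least 2 on that scale, which understates the change of low genes. All tests were 2-sided. There were 23 comparisons. Means are given with SD over libraries, and fold changes with standard error (SE). A total of 17 gene lists with 164 members were fixed before the data were examined, as were the groups, the tests and most alternatives. Lists were tested with camera in limma at a preset correlation between genes of 0.01 and again with an estimated correlation, adjusted over all lists and comparisons of an experiment (353 tests in all). Of 138 list calls at the preset value, 63 held with an estimated correlation, 11 of 25 in the wound course, 52 of 71 in the peptide course and 0 of 42 in the genotype experiment, where the lowest adjusted p with an estimated correlation was 0.0504. With matched members only, a setting described with the naming of genes, 81 list calls were made in place of 138. Lists were shorter in that setting, so a lost call there may reflect list size. The lists are JA biosynthesis, JAZ repressors, phytoalexin synthesis, PR proteins, WRKY factors, early stress regulators, phenylpropanoid, peptide signalling, photosynthesis, circadian clock, senescence, low oxygen response and markers of roots, seeds, dividing cells, vascular tissue, and epidermis and wax.

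The rule for naming genes, fixed at the same time, took from each list the 2 members past the thresholds with the largest change, and in addition the 4 largest rises and falls among genes with a symbol or description. The deposited tables pair no IDs with names, so the second part of the rule named no gene. Symbols of list members come from the fixed lists. Of the 164 members, 133 had a position in the tables. A RefSeq gene table (assembly ASM3414082v1, used for names, chromosomes and spans only, since its build differs from that of the deposited tables) held 62 of them under the same symbol, on the same chromosome and with a similar span. For 64 the symbol was not in that table, and 7 had another chromosome or span. After the data were seen, naming was restricted to the 62 matched members, the 2 receptor loci and LUX, whose symbols come from the fixed lists alone. JAZ10, PRR95, CAB1R and LUX were also followed into comparisons where the rule did not name them, and were chosen for this after their values were seen. A total of 16 further gene families defined by words in gene descriptions could not be formed, because no descriptions were used here. Whether a gene's exons or untranslated regions are covered was not analysed here, for lack of an annotation of the same build.

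Whole read numbers were not recovered from the values. The fragments implied by the deposited 95% intervals, summed over the joined genes, came to 2980000 to 6800000 per library in the wound course, 5390000 to 7510000 in the peptide course and 3450000 to 5980000 in the genotype experiment. They leave out unjoined records and are a measure of relative precision, not of sequencing depth. On annotated genes with more than 40 such fragments over both libraries of a group, both libraries differed by more than counting noise in 22 of 22 groups by a chi-square test. The median squared deviation was 1.09 to 1.83 times that of counting noise. The correlation of log2 values between both libraries of a group, across genes, was 0.962 to 0.988. No pair was counted as 1 library.

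The test was run on simulated data drawn around each gene's mean over all libraries of its experiment, with the spread fitted to it. In each of the 23 comparisons 200 genes were changed by known folds, all with means well above 1 FPKM. Of genes changed 2-fold the test called 32 to 58%, of those changed 3-fold 84 to 100%, of those changed 4-fold 82 to 100%, and of those changed 8-fold 96 to 100%. It called 0 to 7 unchanged genes. Alternatives were FPKM as deposited, quantile normalization, a pseudocount of 0.1, no filter on low values, fits with the compared groups only, other unwounded controls, an estimated correlation and leaving out each library in turn. After seeing the data, a position overlap of 0.5, values net of the difference at 0 min, exchanged unwounded controls for the earliest wound times, genotype fits without wounded transgenic groups, lists of matched members only, and a block on the replicate mark of the titles were added. Calculations outside R used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.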

Results

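Transcript levels were measured by RNA-seq in leaves of the rice cultivar Pusa Basmati 1, in 22 groups of 2 libraries. The wound course held leaves punched along the edges at intervals of 2 cm and collected at 0, 15 and 30 min and 2 h, with unwounded leaves of 0 and 15 min. The peptide course held leaf strips of 2 cm, rested overnight in water and then given OsPep2, OsPep3 or no peptide (mock) for 0 min, 30 min or 2 h. The OsPeps are short peptides of the Pep family, which plants release as danger signals. The genotype experiment held wild type plants, plants labelled as knockout of the receptor-like kinase gene RLK1, and plants overexpressing it, unwounded or 12 h after wounding, and a knockout group labelled cell death. The fragments behind these values, as implied by the deposited intervals, ranged from 2980000 to 7510000 per library.

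The receptor gene was examined first. The labels name it without a locus, so 2 loci carried under such names were fixed in advance, LRR-RLK1 (Os06g0691800, chromosome 6, 28853373 to 28856934) and PSKR1 (Os02g0629400, chromosome 2, 25176174 to 25179701). Coordinates are those of the deposited tables, whose genome build is not given in the sources used here. LRR-RLK1 was at 34.3 and 35.6 scaled FPKM in both unwounded overexpression libraries and at 1.71 and 1.97 in wild type, a log2 fold change of 3.66 (SE 0.1, n = 2 per group, limma with Benjamini-Hochberg adjustment, adjusted p = 1.2e-08). Wounded overexpression libraries held 52.9 and 52.2, and wounded wild type libraries 1.43 and 1.67. Unwounded libraries labelled knockout held 2.3 and 2.48, and those of the cell death group 2.27 and 2.47, neither below unwounded wild type. Wounded knockout libraries, at 0.781 and 0.848, were below wounded wild type. The change with wounding differed between these genotypes by -0.75 on the log2 scale (SE 0.13, limma with Benjamini-Hochberg adjustment, adjusted p = 0.0015), short of the fold threshold. The unwounded libraries showed no loss of this transcript, and every direction drawn from the knockout libraries rests on their label. PSKR1 was at 0.405 and 0.513 in overexpression and 0.611 and 0.524 in wild type libraries, a log2 difference of -0.1 (SE 0.11) that did not pass the test (limma, Benjamini-Hochberg adjusted p = 0.51).

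**Figure D1:**
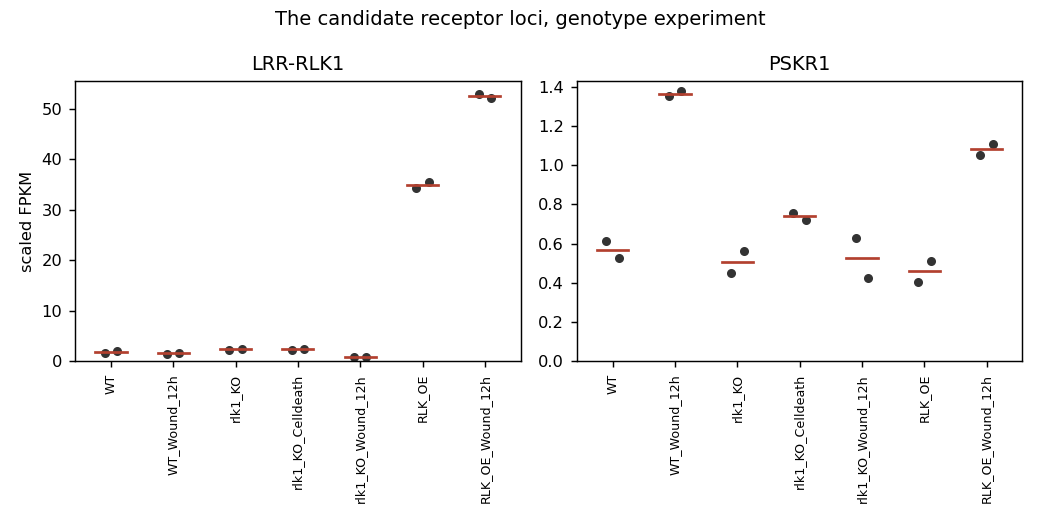
Scaled FPKM of LRR-RLK1 and PSKR1 on the vertical axes in the 7 groups of the genotype experiment, with 1 point per library and a line at the mean of 2. LRR-RLK1 stood at 34.3 to 52.9 in the overexpression libraries and at no more than 2.48 in the others.

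Wounded leaves of 15 min were compared with unwounded leaves of 15 min to show the early transcript response to wounding. Of 13488 genes tested, 783 rose and 118 fell. JAZ10 (Os03g0181100), a repressor of jasmonate signalling, was at 769 ± 10 scaled FPKM (SD, n = 2) against 13.7 ± 0.25, a log2 fold change of 5.71 (SE 0.07, limma with Benjamini-Hochberg adjustment, adjusted p = 5.9e-10). The defence transcription factor WRKY71 (Os02g0181300) reached 644 ± 8.9 against 15.9 ± 0.31, and WRKY76 (Os09g0417600) 135 ± 2.3 against 0.769 ± 0.016. Among WRKY factors 9 of 11 rose and none fell, with the same 9 adjusted over the list alone and a median log2 fold change of 3.18. JAZ repressors rose in 4 of 8, also 4 adjusted over the list alone, with a median of 1.68, and phenylpropanoid genes in 3 of 8 with a median of 0.79. These 3 lists passed camera's test, each also with an estimated correlation (Benjamini-Hochberg adjusted p = 0.0166). JA biosynthesis rose in 2 of 7, among them the allene oxide synthase gene AOS2 at 11.4 ± 0.21 against 1.27 ± 0.16, but the list's call was lost (adjusted p = 0.204 with an estimated correlation). So were those of early stress regulators, of which 4 of 6 rose (adjusted p = 0.0567 with an estimated correlation), PR proteins, 3 of 6 (adjusted p = 0.0928 with an estimated correlation), and photosynthesis, 2 of 17 (adjusted p = 0.0508 with an estimated correlation), whose median turned to -0.75 against unwounded leaves of 0 min, a control exchanged after the data were seen. With matched members only, the calls of phenylpropanoid, PR proteins and early stress regulators were lost. The matched members tested were 4CL3 and CAD2, Cht1 alone, and RBOHB alone. Lists this short cannot show whether the calls rested on the unmatched members. Against unwounded leaves of 0 min, phenylpropanoid genes rose in 7 of 8 (median 2.43), JAZ repressors in 4 of 8 (median 1.75) and WRKY factors in 9 of 11 (median 2.56).

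At 30 min after wounding, set against the 4 unwounded libraries of both times, 1439 genes rose and 604 fell. Against this pooled control, SE and p-values rest on the spread within groups and leave out the difference between both unwounded times. WRKY76, for one, was at 7.95 ± 0.25 scaled FPKM in unwounded leaves of 0 min and 0.769 ± 0.016 in those of 15 min (SD, n = 2). Unwounded leaves of 30 min are not among the groups, so elapsed time and wounding are not separated in this comparison. All 8 JAZ repressors tested rose, with a median log2 fold change of 3.53, as did all 11 WRKY factors, with a median of 2.52, and the same numbers passed adjusted over the list alone. WRKY76 was at 791 ± 1.4 scaled FPKM (SD, n = 2) against 4.36 ± 4.2 (SD, n = 4), a log2 fold change of 7.64 (SE 0.1, limma with Benjamini-Hochberg adjustment, adjusted p = 1.9e-10), and WRKY71 was at 1630 ± 11 against 24.5 ± 10. JAZ10 reached 1650 ± 15 against 42.1 ± 33, and AOC, the allene oxide cyclase of jasmonate synthesis, 262 ± 29 against 74.4 ± 14. RBOHB, an NADPH oxidase gene, and CEBiP, a chitin receptor gene, were at 35.1 ± 1.2 against 8.53 ± 1.6 and 392 ± 7.9 against 90.2 ± 14. The JAZ and WRKY lists passed camera with an estimated correlation, at Benjamini-Hochberg adjusted p = 0.0166 and 0.0312. Early stress regulators rose in 5 of 6, a list call that was lost (adjusted p = 0.0657 with an estimated correlation), and photosynthesis genes rose in 3 of 17 with none falling, a call lost under quantile normalization. Against unwounded leaves of 0 min alone 0 of 17 photosynthesis genes rose (median 0.23), and against those of 15 min alone 13 did (median 1.36). On FPKM as deposited the balance of calls turned, with 960 higher and 1470 lower, and at a pseudocount of 0.1 it was 1668 and 1142.

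By 2 h after wounding, 1599 genes had risen and 1305 had fallen against the same 4 unwounded libraries, with the same limit on SE and p-values. All 8 JAZ repressors rose, at a median log2 fold change of 3.53 (8 adjusted over the list alone, camera with an estimated correlation, Benjamini-Hochberg adjusted p = 0.0169). JAZ11 (Os03g0180900) was at 47.7 ± 1.7 scaled FPKM (SD, n = 2) against 0.549 ± 0.11 (SD, n = 4), and JAZ8 (Os09g0439200) at 40.6 ± 0.86 against 0.592 ± 0.085. JAR1, which conjugates jasmonate to isoleucine, was at 95.6 ± 2.9 against 14.9 ± 2.4 (log2 fold change 2.62, SE 0.06, limma with Benjamini-Hochberg adjustment, adjusted p = 4.3e-09), and OPR7, an enzyme of jasmonate synthesis, at 47.5 ± 5 against 14.1 ± 1.6. RBOHB had risen to 84.5 ± 2.5 against 8.53 ± 1.6. JA biosynthesis rose in 5 of 7 (adjusted p = 0.17 with an estimated correlation), early stress regulators in 5 of 6 (adjusted p = 0.118 with an estimated correlation) and WRKY factors in 5 of 11 with 1 lower (adjusted p = 0.204 with an estimated correlation), so that these list calls were lost. Photosynthesis genes fell in 5 of 17 and rose in 1, which was PORA, a chlorophyll synthesis gene, at 142 ± 3.5 against 52 ± 37 (adjusted p of the list = 0.053 with an estimated correlation, camera). These falls depended on the control, with 13 of 17 lower against unwounded leaves of 0 min alone (median -1.42) and 1 lower and 1 higher against those of 15 min alone (median -0.31). PORA fell short of the fold threshold against the former and JA biosynthesis lost its list call at the preset correlation against the latter. The clock gene PRR1 was at 15.9 ± 0.57 against 5.39 ± 0.36, and 4 of 6 clock genes rose, although the list did not pass camera (Benjamini-Hochberg adjusted p = 0.0501). It passed at the preset correlation against unwounded leaves of 15 min alone (adjusted p = 0.0173) and not against those of 0 min alone (adjusted p = 0.172). Unwounded leaves of 2 h are not among the groups, so hours of the day and wounding are not separated in the 2 h changes. In the peptide course, some clock genes also rose between 0 min and 2 h in mock strips, which were given no peptide.

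**Figure D2:**
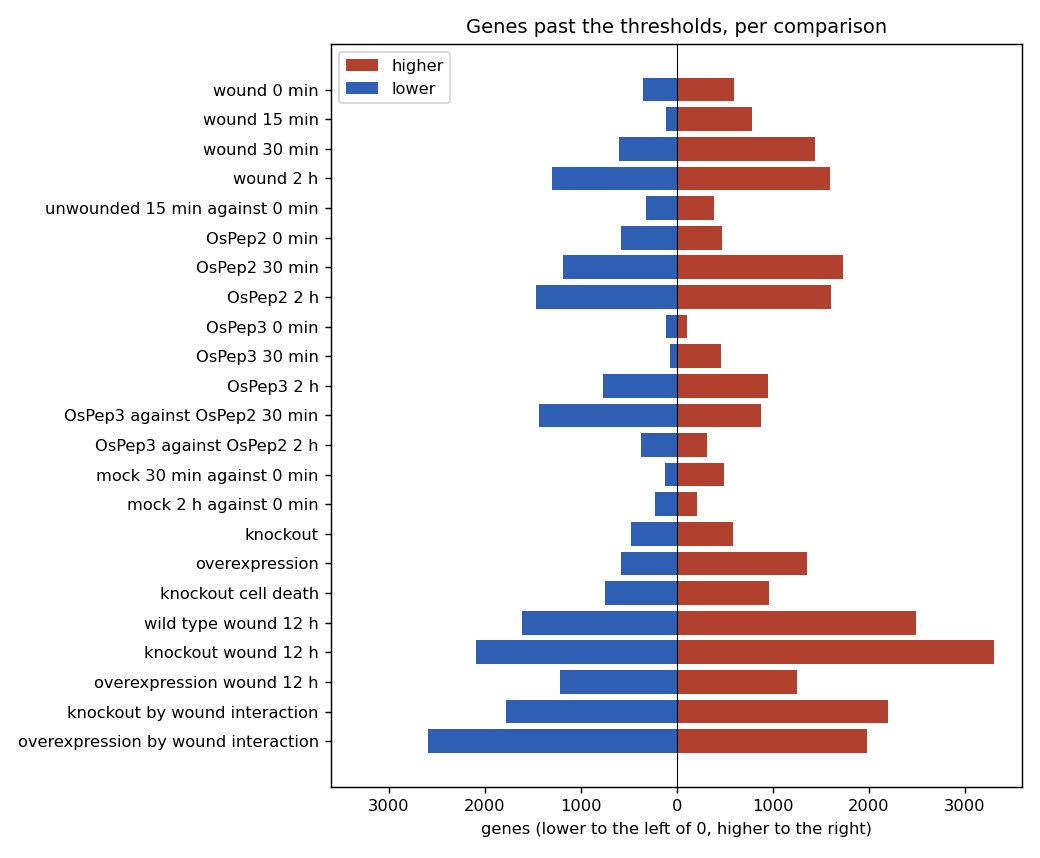
Number of genes past the thresholds in each of the 23 comparisons, with bars from 0 for genes that were higher (right) and lower (left). The longest bar to the right belongs to the wounded knockout leaves at 12 h, with 3299 genes, and the longest to the left to the interaction of overexpression and wounding, with 2597.

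Leaves collected at once after wounding differed from unwounded leaves of 0 min in 941 genes, 590 higher and 351 lower (818 and 185 on FPKM as deposited). The phenylpropanoid genes 4CL3 and CAD2, which act in lignin synthesis, were at 80 ± 2.4 against 11 ± 0.63 and 32.8 ± 4.1 against 2.09 ± 0.18 scaled FPKM (SD, n = 2). That list rose in 6 of 8 with none falling (6 adjusted over the list alone, median log2 fold change 2.18), and photosynthesis genes fell in 5 of 17 (median -0.89), both also with an estimated correlation (camera, Benjamini-Hochberg adjusted p = 0.0166). PR proteins rose in 3 of 6 (adjusted p = 0.0657 with an estimated correlation). Early stress regulators, none of which passed alone, had a median of -0.77 (adjusted p = 0.166 with an estimated correlation). JAZ10 fell to 18 ± 0.87 from 70.6 ± 8.5. The unwounded leaves of 15 min differed from those of 0 min in the same lists, as phenylpropanoid genes were higher in 6 of 8 (median 1.3) and photosynthesis genes lower in 10 of 17 (median -1.08), both at adjusted p = 0.0166 with an estimated correlation in camera with Benjamini-Hochberg adjustment. There JAZ10 was at 13.7 ± 0.25 against 70.6 ± 8.5, 4CL3 at 35.4 ± 1.2 against 11 ± 0.63, and 382 genes were higher and 324 lower. Against unwounded leaves of 15 min, a control exchanged after the data were seen, 121 genes separated the just wounded leaves in place of 941, the photosynthesis median turned to 0.21, and JAZ10 turned to a log2 fold change of 0.37. Phenylpropanoid genes still rose there in 4 of 8 (median 0.87), WRKY factors in 3 of 11 and PR proteins in 2 of 6 (camera at the preset correlation, Benjamini-Hochberg adjusted p = 1.88e-08, 9.17e-06 and 1.46e-05). On FPKM as deposited, 1140 genes differed between the unwounded times in place of 706, with 1013 higher and 127 lower.

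OsPep2 was compared with mock at 30 min to show the transcripts that follow the peptide. It changed 2919 of 14142 genes, 1735 higher and 1184 lower. WRKY24 (Os01g0826400) was at 981 ± 14 scaled FPKM against 10.4 ± 1.2 (SD, n = 2), a log2 fold change of 6.43 (SE 0.08, limma with Benjamini-Hochberg adjustment, adjusted p = 7.2e-14). MPK3, a kinase of the defence MAP kinase cascade, was at 1330 ± 7.9 against 35.7 ± 0.54, JAZ10 at 4400 ± 81 against 211 ± 2.1 and JAZ9 at 565 ± 0.4 against 12.5 ± 0.0052. Both receptor loci rose, LRR-RLK1 to 12.2 ± 0.22 against 1.73 ± 0.44 and PSKR1 to 11.1 ± 0.026 against 2.06 ± 0.35. WRKY factors rose in 9 of 12 (median 3.38), JAZ repressors in 6 of 8 (median 2.26), early stress regulators in 8 of 12 with 1 lower (median 1.54) and peptide signalling genes in 4 of 4 (median 1.79), while PR proteins fell in 3 of 4 (median -1.19). Adjusted over the list alone, the numbers past the thresholds were 9, 6, 9, 4 and 3. With an estimated correlation, camera gave Benjamini-Hochberg adjusted p = 0.0112, 0.0091, 0.0172, 0.0497 and 0.0313 for these 5 lists. Genes fixed as Pep receptors in the peptide signalling list lay below 1 FPKM in the peptide course and were not tested there. They were at 0.315 and 0.112 scaled FPKM with OsPep2 against 0.404 and 0.17 in mock. The former was tested in the wound course and rose at 2 h, to 6.55 ± 0.064 from 0.161 ± 0.069 (limma with Benjamini-Hochberg adjustment, adjusted p = 6.6e-08). Phenylpropanoid genes rose in 3 of 8 (adjusted p = 0.105 with an estimated correlation) and markers of epidermis and wax in 2 of 3 (adjusted p = 0.0919 with an estimated correlation). Photosynthesis genes had a median of 0.43 that turned to -0.08 on FPKM as deposited and to -0.12 under quantile normalization (adjusted p = 0.189 with an estimated correlation, camera). The split of calls also turned on FPKM as deposited, with 1163 higher and 2329 lower.

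OsPep3 at 30 min changed 528 genes, 457 higher and 71 lower. Of the genes named for OsPep2, WRKY24 was at 178 ± 2.5 scaled FPKM against 10.4 ± 1.2 (SD, n = 2; log2 fold change 3.98, SE 0.08, limma with Benjamini-Hochberg adjustment, adjusted p = 3.3e-11), MPK3 at 205 ± 0.27 against 35.7 ± 0.54 and JAZ10 at 1530 ± 59 against 211 ± 2.1. WRKY factors rose in 8 of 12 (median 1.92), JAZ repressors in 5 of 8 (median 1.56) and phenylpropanoid genes in 3 of 8 (median 0.47), with 8, 5 and 3 adjusted over the list alone and Benjamini-Hochberg adjusted p = 0.00775, 0.00775 and 0.0157 in camera with an estimated correlation. JA biosynthesis rose in 2 of 7, a list call that was lost (adjusted p = 0.0813 with an estimated correlation). The chlorophyll breakdown gene SGR was at 70.3 ± 1.1 against 24.3 ± 0.08. LRR-RLK1, at 4.02 ± 0.55 against 1.73 ± 0.44, and PSKR1, at 3.11 ± 0.091 against 2.06 ± 0.35, stayed below the fold threshold.

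The peptides were then compared directly at 30 min, since the labels name both without giving a dose. A total of 2314 genes differed, 878 higher and 1436 lower with OsPep3. MPK3 differed by a log2 fold change of -2.7 (SE 0.04, n = 2 per group, limma with Benjamini-Hochberg adjustment, adjusted p = 2.5e-12), WRKY24 by -2.45 (SE 0.08), JAZ9 by -2.5 (SE 0.23) and JAZ10 by -1.52 (SE 0.12). PSKR1 was lower with OsPep3, by -1.56 (SE 0.09), and so was LRR-RLK1, by -1.4 (SE 0.12), a difference that fell short of the fold threshold on FPKM as deposited. WRKY factors were lower in 6 of 12 and higher in 1 (median -1.06), while PR proteins were higher in 4 of 4 (median 1.87) and phytoalexin genes in 4 of 10 (median 0.9), with 7, 4 and 4 adjusted over the list alone and Benjamini-Hochberg adjusted p = 0.022, 0.0172 and 0.0173 in camera with an estimated correlation. The diterpenoid oxidase gene CYP71Z7 was at 1.98 ± 0.25 with OsPep3, at 0.0436 ± 0.062 with OsPep2 and at 1.13 ± 0.099 in mock. A higher value with OsPep3 than with OsPep2 is not by itself a rise over mock, as PR proteins fell with OsPep2. JAZ repressors, lower in 4 of 8 (median -1.06), lost their list call under quantile normalization. The balance of calls turned on FPKM as deposited, with 1912 higher and 815 lower.

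**Figure D3:**
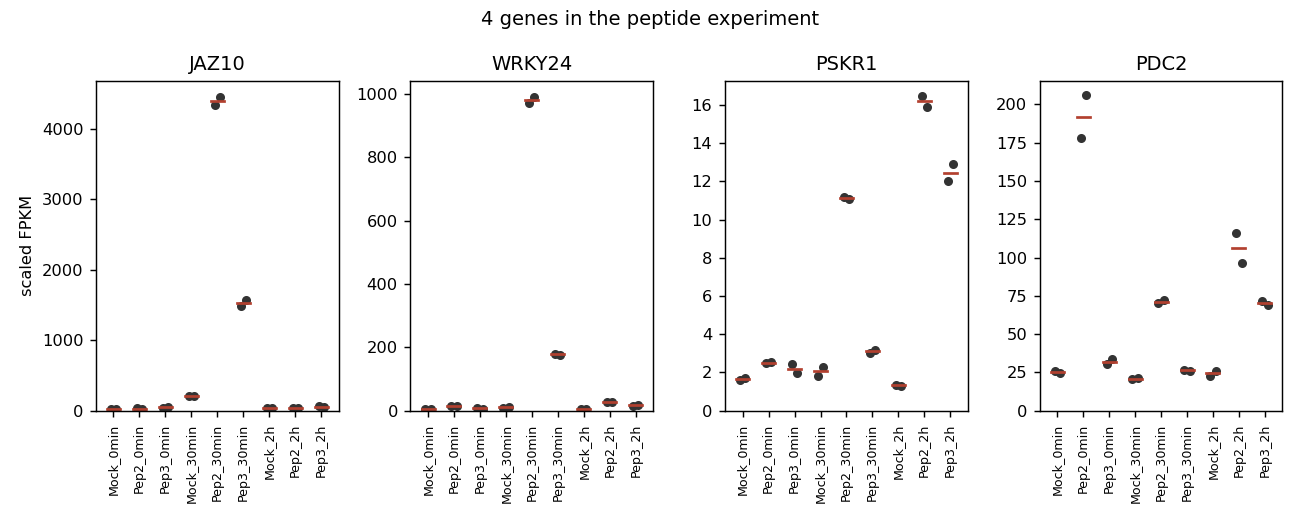
Scaled FPKM of JAZ10, WRKY24, PSKR1 and PDC2 on the vertical axes in the 9 groups of the peptide course, with 1 point per library and a line at the mean of 2. JAZ10 and WRKY24 peaked at 30 min, at 4400 and 981 with OsPep2, PSKR1 was highest at 2 h, and PDC2 was already at 192 at 0 min with OsPep2.

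After 2 h, OsPep2 changed 3070 genes, 1605 higher and 1465 lower, and OsPep3 1712 genes, 947 higher and 765 lower. PSKR1 was at 16.2 ± 0.44 scaled FPKM with OsPep2 and 12.4 ± 0.62 with OsPep3 against 1.34 ± 0.044 in mock (SD, n = 2), log2 fold changes of 2.88 and 2.52 (SE 0.09 each, limma with Benjamini-Hochberg adjustment, adjusted p = 1.8e-10 and 1.1e-09). JAZ10, at 32.9 ± 2.1 with OsPep2 and 39.3 ± 5.8 in mock, did not pass the test at 2 h. JAZ repressors rose in 1 of 8 with OsPep2, without passing camera (Benjamini-Hochberg adjusted p = 0.0568), and in 4 of 8 with OsPep3 (4 adjusted over the list alone, median 1.02; adjusted p = 0.022 with an estimated correlation, camera). CAD2 was at 240 ± 3 and 173 ± 9.4 against 51.5 ± 0.53, and the clock gene PRR95 fell to 11.6 ± 0.29 and 20.9 ± 0.43 from 51.7 ± 0.79. PORA fell to 71.7 ± 2.9 and 64.4 ± 0.56 from 355 ± 10. JA biosynthesis rose in 4 of 7 with either peptide (4 adjusted over the list alone in each), with Benjamini-Hochberg adjusted p = 0.0379 and 0.0358 in camera with an estimated correlation. Phenylpropanoid genes rose in 6 of 8 with OsPep2, a list call that was lost (adjusted p = 0.0566 with an estimated correlation), and in 5 of 8 with OsPep3 (adjusted p = 0.0351 with an estimated correlation, camera). With OsPep3, photosynthesis genes fell in 15 of 18 (median -1.24) and phytoalexin genes rose in 7 of 10 (median 1.11), with 15 and 7 adjusted over the list alone (adjusted p = 0.0137 and 0.0122 with an estimated correlation, camera). With OsPep2 photosynthesis genes fell in 4 of 18 and rose in 1 (adjusted p = 0.18 with an estimated correlation), so that list call was lost. The peptides themselves differed in 682 genes, 309 higher and 373 lower with OsPep3, a balance that turned on FPKM as deposited (468 and 264). DREB1A, a cold and stress response factor, was at 14.2 ± 2.5 with OsPep3 and 69.8 ± 1.2 with OsPep2 (log2 fold change -2.23, SE 0.15, limma with Benjamini-Hochberg adjustment, adjusted p = 3.8e-07). With OsPep3, phytoalexin genes were higher in 2 of 10 (median 0.67) and photosynthesis genes lower in 5 of 18 (median -0.62), both also with an estimated correlation (adjusted p = 0.0172 and 0.022, camera). At a pseudocount of 0.1 this comparison gave 1142 genes.

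At 0 min the peptide groups already differed from mock, OsPep2 in 1053 genes (473 higher, 580 lower) and OsPep3 in 218 (104 higher, 114 lower). PDC2, a pyruvate decarboxylase gene of the low oxygen response, was at 192 ± 20 scaled FPKM with OsPep2, 32 ± 2.1 with OsPep3 and 25.1 ± 0.85 in mock (SD, n = 2; OsPep2 log2 fold change 2.88, SE 0.1, limma with Benjamini-Hochberg adjustment, adjusted p = 7.6e-10). PDC2 was the only member of its list tested there, and the list call was lost (adjusted p = 0.06 with an estimated correlation, camera), as it was without the filter on low values. The lipoxygenase gene LOX9 was at 18.9 ± 0.88 with OsPep2 against 3.55 ± 0.18, and RBOHB fell to 4.71 ± 0.13 from 16.7 ± 0.28. WRKY factors rose in 7 of 12 with OsPep2 (median 1.16), PR proteins in 4 of 4 (median 1.82), and photosynthesis genes fell in 8 of 18 (median -0.83), with 7, 4 and 8 adjusted over the list alone and Benjamini-Hochberg adjusted p = 0.00775, 0.0091 and 0.0112 in camera with an estimated correlation. With OsPep3, JAZ10 was at 45.6 ± 3.9 against 19.1 ± 2.5, and PR proteins rose in 3 of 4 (median 1.35; adjusted p = 0.00775 with an estimated correlation, camera). Net of the difference at 0 min, an alternative added after seeing the data, OsPep2 changed 2476 genes at 30 min and 2426 at 2 h, and OsPep3 642 and 1371. These net values ended the list calls of JA biosynthesis with OsPep2 at 2 h and with OsPep3 at 30 min and of JAZ repressors with OsPep3 at 2 h, and turned the photosynthesis median with OsPep2 at 2 h to 0.41. PORA with OsPep2 at 2 h, PRR95 with OsPep3 at 2 h and SGR with OsPep3 at 30 min fell short of the fold threshold on them. At a pseudocount of 0.1, OsPep3 at 0 min gave 411 genes.

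Mock strips changed with time as well, in 611 genes at 30 min (490 higher, 121 lower) and 438 at 2 h (214 higher, 224 lower) against mock at 0 min. At 30 min JAZ repressors rose in 7 of 8 (median log2 fold change 2.94), WRKY factors in 6 of 12 with 1 lower (median 1.13), JA biosynthesis in 3 of 7 (median 0.67) and PR proteins in 4 of 4 (median 2.15), with 7, 7, 3 and 4 adjusted over the list alone. In camera with an estimated correlation their Benjamini-Hochberg adjusted p values were 0.00571, 0.00775, 0.00775 and 0.00775. JAZ10 was at 211 ± 2.1 scaled FPKM against 19.1 ± 2.5, and LOX9 at 32.2 ± 1.1 against 3.55 ± 0.18 (SD, n = 2). At 2 h PRR95 was at 51.7 ± 0.79 against 21.4 ± 0.21, and clock genes rose in 2 of 5 (2 adjusted over the list alone, median 0.92, adjusted p = 0.0153 with an estimated correlation, camera). JAZ repressors were then higher in 3 of 8 (median 0.97, adjusted p = 0.00775 with an estimated correlation, camera). At a pseudocount of 0.1 the 2 h comparison gave 735 genes.

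In unwounded leaves, the libraries labelled knockout differed from wild type in 1062 of 14447 genes, 587 higher and 475 lower. WRKY24 was at 1.53 ± 0.35 scaled FPKM against 13.6 ± 0.18 (SD, n = 2), a log2 fold change of -2.53 (SE 0.13, limma with Benjamini-Hochberg adjustment, adjusted p = 1.6e-06), and WRKY76 was listed at 0 in both knockout libraries against 2.99 ± 0.57. JAZ10 was at 0.559 ± 0.49 against 13.3 ± 0.37, MPK3 at 3.8 ± 0.3 against 9.9 ± 0.93 and SGR at 98.7 ± 9 against 229 ± 3.6. The light harvesting gene CAB2R was at 1720 ± 23 against 305 ± 3.8, and PORA at 21.9 ± 0.3 against 0.0717 ± 0.1. WRKY factors were lower in 8 of 13 (8 adjusted over the list alone, median -1.29), which passed camera at the preset correlation (Benjamini-Hochberg adjusted p = 1.35e-09) and was lost at adjusted p = 0.0504 with an estimated correlation. JAZ repressors were lower in 3 of 8, senescence genes in 3 of 5 and early stress regulators in 2 of 10, and photosynthesis genes higher in 7 of 17 (adjusted p = 0.0559 with an estimated correlation for each of these 4 lists). Phenylpropanoid genes fell in 2 of 8 (adjusted p = 0.0681 with an estimated correlation).

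Overexpression leaves differed from wild type in 1931 genes, 1351 higher and 580 lower (1633 and 1145 at a pseudocount of 0.1, 1049 and 861 on FPKM as deposited). The defence factors WRKY62 (Os09g0417800) and WRKY76 were at 75.8 ± 0.04 and 93.4 ± 16 scaled FPKM against 1.87 ± 0.72 and 2.99 ± 0.57 (SD, n = 2), log2 fold changes of 4.77 (SE 0.21) and 4.56 (SE 0.17; limma with Benjamini-Hochberg adjustment, adjusted p = 2.4e-07 and 7.5e-08). CAD2 was at 117 ± 9.7 against 13.3 ± 1.9, 4CL3 at 99.1 ± 2.2 against 14.6 ± 1.2, and CEBiP at 38.1 ± 1.2 against 5.41 ± 0.43. CAB2R was at 3030 ± 190 against 305 ± 3.8, and SGR fell to 56.5 ± 1.5 from 229 ± 3.6. Phenylpropanoid genes rose in 7 of 8 (median 2.87; adjusted p = 0.0607 with an estimated correlation), WRKY factors in 9 of 13 (median 2.02; adjusted p = 0.0564 with an estimated correlation), phytoalexin genes in 6 of 8 (median 1.65; adjusted p = 0.0506 with an estimated correlation) and photosynthesis genes in 11 of 17 (median 1.27; adjusted p = 0.0504 with an estimated correlation). The same numbers passed adjusted over the list alone. Senescence genes fell in 4 of 5 (median -2; adjusted p = 0.0504 with an estimated correlation), and PR proteins rose in 2 of 4 and peptide signalling genes, LRR-RLK1 among them, in 3 of 5 (adjusted p = 0.0831 with an estimated correlation for both). The same 2 wild type libraries served as control for both transgenic lines. Against them, photosynthesis genes were higher and senescence genes lower in both lines, while WRKY factors were lower in the knockout and higher with overexpression. For changes shared by both lines, a peculiarity of these wild type leaves and an effect of genotype cannot be told apart.

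Knockout leaves labelled cell death were compared with the other unwounded knockout leaves, and 964 genes were higher and 747 lower. All 8 phytoalexin genes tested rose (8 adjusted over the list alone, median log2 fold change 1.95), with KSL7, a diterpene synthase gene, at 7.5 ± 1.4 scaled FPKM against 0.0118 ± 0.017 (SD, n = 2; log2 fold change 3.06, SE 0.21, limma with Benjamini-Hochberg adjustment, adjusted p = 4.3e-06). That list passed camera at the preset correlation and was lost at adjusted p = 0.0504 with an estimated correlation. AOS2 was at 8.66 ± 0.57 against 0.109 ± 0.15, CAD2 at 70.8 ± 3.8 against 10.7 ± 1.2 and WRKY24 at 16.2 ± 2.3 against 1.53 ± 0.35. The chlorophyll breakdown genes SGR and NYC1 were at 274 ± 20 against 98.7 ± 9 and 40.7 ± 0.36 against 14.4 ± 0.064, and CAB2R fell to 315 ± 5.3 from 1720 ± 23. WRKY factors rose in 6 of 13 (adjusted p = 0.0607 with an estimated correlation), senescence genes in 3 of 5 (adjusted p = 0.121 with an estimated correlation) and clock genes in 3 of 6 (adjusted p = 0.0681 with an estimated correlation), while photosynthesis genes fell in 8 of 17 (adjusted p = 0.0559 with an estimated correlation). The clock gene PRR95 was at 193 ± 2.2 against 75.7 ± 3.2. The cell death group was not tested against wild type, whose unwounded leaves held similar values for CAB2R (305 ± 3.8), SGR (229 ± 3.6) and WRKY24 (13.6 ± 0.18). Wild type held lower values for KSL7 (0.00926 ± 0.013), AOS2 (0.346 ± 0.023), CAD2 (13.3 ± 1.9), NYC1 (26.1 ± 0.94) and PRR95 (95.9 ± 4.1).

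Wild type leaves 12 h after wounding differed from unwounded wild type leaves in 4099 genes, 2490 higher and 1609 lower. The light harvesting gene CAB1R was at 23 ± 1 scaled FPKM against 3850 ± 63 (SD, n = 2), a log2 fold change of -7.32 (SE 0.08, limma with Benjamini-Hochberg adjustment, adjusted p = 1.1e-11), and photosynthesis genes fell in 12 of 17 and rose in 1 (13 adjusted over the list alone, median -2.67; adjusted p = 0.0504 with an estimated correlation). Cht1, a chitinase gene, was at 37.2 ± 4.8 against 0.436 ± 0.33, and PR proteins rose in 3 of 4 (adjusted p = 0.103 with an estimated correlation). JAZ11 was at 41 ± 0.8 against 2.3 ± 0.048 and WRKY62 at 18.9 ± 2.5 against 1.87 ± 0.72. Of 6 clock genes 1 rose and 2 fell, and the list did not pass camera (Benjamini-Hochberg adjusted p = 0.797). PRR95 fell to 0.955 ± 0.13 from 95.9 ± 4.1 and LUX (Os01g0971800) rose to 28.6 ± 1.3 from 0.203 ± 0.026. LSI1, a silicon transporter gene fixed as a root marker, fell to 5.69 ± 0.58 from 22.3 ± 1.7. No unwounded leaves labelled 12 h are among the groups, so hours of the day and wounding are not separated in this comparison. With FPKM as deposited the PR protein list call was lost and calls split into 3818 higher and 1170 lower.

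In the libraries labelled knockout, 5394 genes differed 12 h after wounding, 3299 higher and 2095 lower. By correlation across genes, at 0.962 against 0.983 to 0.988 in the other groups, the libraries of this wounded group differed most from each other. So they did by median squared deviation, at 1.83 times counting noise against at most 1.42. By mean squared deviation they did not, at 2.33 times counting noise against 3.33 in mock strips of 30 min. With a library of the comparison left out, 5311 to 5592 genes differed. CAB1R was at 13.8 ± 2.3 scaled FPKM against 3300 ± 16 (SD, n = 2), and photosynthesis genes fell in 15 of 17 (15 adjusted over the list alone, median -4.56; adjusted p = 0.0504 with an estimated correlation). JAZ8 was at 92.9 ± 3.5 against 1.22 ± 0.53, a log2 fold change of 5.42 (SE 0.18, limma with Benjamini-Hochberg adjustment, adjusted p = 7.9e-09), and JAZ10 at 46 ± 1.1 against 0.559 ± 0.49. JAZ repressors rose in 7 of 8 (median 3.19) and WRKY factors in 10 of 13 (median 2.02), both at adjusted p = 0.0681 with an estimated correlation. Phenylpropanoid genes rose in 5 of 8 (adjusted p = 0.12 with an estimated correlation), with CAD2 at 172 ± 16 against 10.7 ± 1.2. CESA7 and CESA9, cellulose synthase genes of secondary walls fixed as vascular markers, were at 4.14 ± 0.46 against 0.0207 ± 0.029 and 4.89 ± 0.5 against 0.129 ± 0.074. PRR95 fell to 0.306 ± 0.13 from 75.7 ± 3.2, and LUX stood at 36.4 and 34.2 in the wounded libraries. Under quantile normalization the split was 2644 higher and 2719 lower.

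Overexpression leaves at 12 h after wounding differed from unwounded ones in 2460 genes, 1247 higher and 1213 lower. WRKY76 and WRKY62 fell to 0.963 ± 0.21 and 0.752 ± 0.34 scaled FPKM from 93.4 ± 16 and 75.8 ± 0.04 (SD, n = 2), log2 fold changes of -5.58 (SE 0.17) and -5.47 (SE 0.21; limma with Benjamini-Hochberg adjustment, adjusted p = 1.8e-08 and 8.4e-08). CAD2 fell to 12.9 ± 0.086 from 117 ± 9.7, and phenylpropanoid genes fell in 6 of 8 (6 adjusted over the list alone, median -2.78; adjusted p = 0.0559 with an estimated correlation). Phytoalexin genes fell in 5 of 8 (adjusted p = 0.0559 with an estimated correlation), WRKY factors in 7 of 13 with 1 higher (adjusted p = 0.116 with an estimated correlation) and photosynthesis genes in 10 of 17 with 1 higher (adjusted p = 0.0504 with an estimated correlation). JAZ8 rose to 37.2 ± 0.83 from 2.01 ± 0.47, and JAZ repressors rose in 6 of 8 (median 1.74; adjusted p = 0.0844 with an estimated correlation), a list call also lost at a pseudocount of 0.1. Senescence genes rose in 3 of 5 (adjusted p = 0.0681 with an estimated correlation). CAB1R, at 4430 ± 94 against 5710 ± 160, and PRR95, at 114 ± 5.2 against 57.3 ± 2.8, did not pass the fold threshold, and LUX stood at 0.21 and 0.489.

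**Figure D4:**
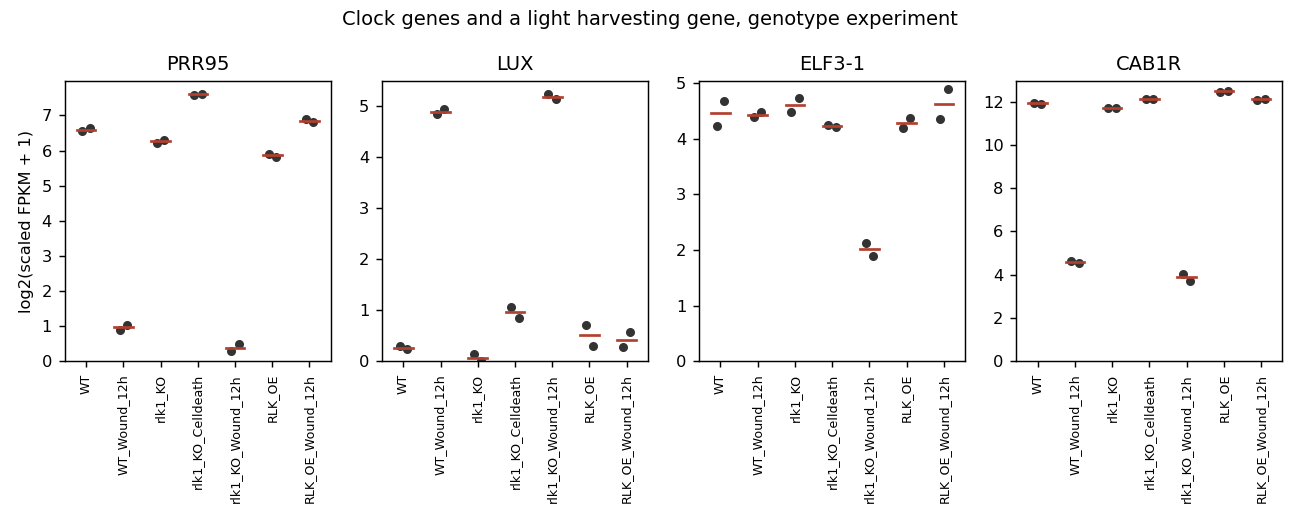
Log2(scaled FPKM + 1) of the clock genes PRR95, LUX and ELF3-1 and the light harvesting gene CAB1R on the vertical axes in the 7 groups of the genotype experiment, with 1 point per library and a line at the mean of 2. Wounded overexpression libraries lie with the unwounded ones for PRR95, LUX and CAB1R, apart from wounded wild type and knockout libraries.

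The change with wounding was compared between genotypes by interaction terms. Such a term also holds any difference between the unwounded groups. For JAZ10, JAZ8 and CAD2 that difference was -3.23, -0.88 and -0.29 on the log2 scale in knockout against wild type. WRKY62 and WRKY76 were already higher in unwounded overexpression than in wild type leaves, while CAB1R and PRR95 differed mainly in wounded leaves. Between knockout and wild type the change with wounding differed in 3981 genes, 2204 with a higher and 1777 with a lower change in the knockout. The interaction was 3.98 on the log2 scale for JAZ8 (SE 0.26), 3.95 for JAZ10 (SE 0.28) and 3.3 for CAD2 (SE 0.16; limma with Benjamini-Hochberg adjustment, adjusted p = 2.3e-06, 3.9e-06 and 4.3e-07), and JAZ repressors had a median of 2.01 with 5 of 8 higher (adjusted p = 0.0681 with an estimated correlation). WRKY factors were higher in 7 of 13 (adjusted p = 0.0954 with an estimated correlation), phenylpropanoid genes in 5 of 8 (adjusted p = 0.103 with an estimated correlation) and both vascular markers (adjusted p = 0.108 with an estimated correlation). Between overexpression and wild type the change differed in 4581 genes, 1984 higher and 2597 lower. The interaction was -8.28 for WRKY62 (SE 0.3), -7.03 for WRKY76 (SE 0.23), 6.96 for CAB1R (SE 0.12) and 6.62 for PRR95 (SE 0.12; limma with Benjamini-Hochberg adjustment, adjusted p = 2.2e-08, 1.4e-08, 2.1e-10 and 3.4e-10). PR proteins were lower in 4 of 4 (median -5.19; adjusted p = 0.0658 with an estimated correlation), phytoalexin genes in 7 of 8 (median -1.64; adjusted p = 0.0669 with an estimated correlation), WRKY factors in 8 of 13 (median -1.36; adjusted p = 0.0831 with an estimated correlation) and phenylpropanoid genes in 6 of 8 with 1 higher (median -3.11; adjusted p = 0.12 with an estimated correlation). Photosynthesis genes were higher in 10 of 17 and lower in 3 (median 2.06; adjusted p = 0.146 with an estimated correlation). The matched members alone, CAB1R, CAB2R, PORA and PORB, turned that median to -0.79. On FPKM as deposited the knockout interaction split turned, with 1425 higher and 3314 lower.

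**Figure D5:**
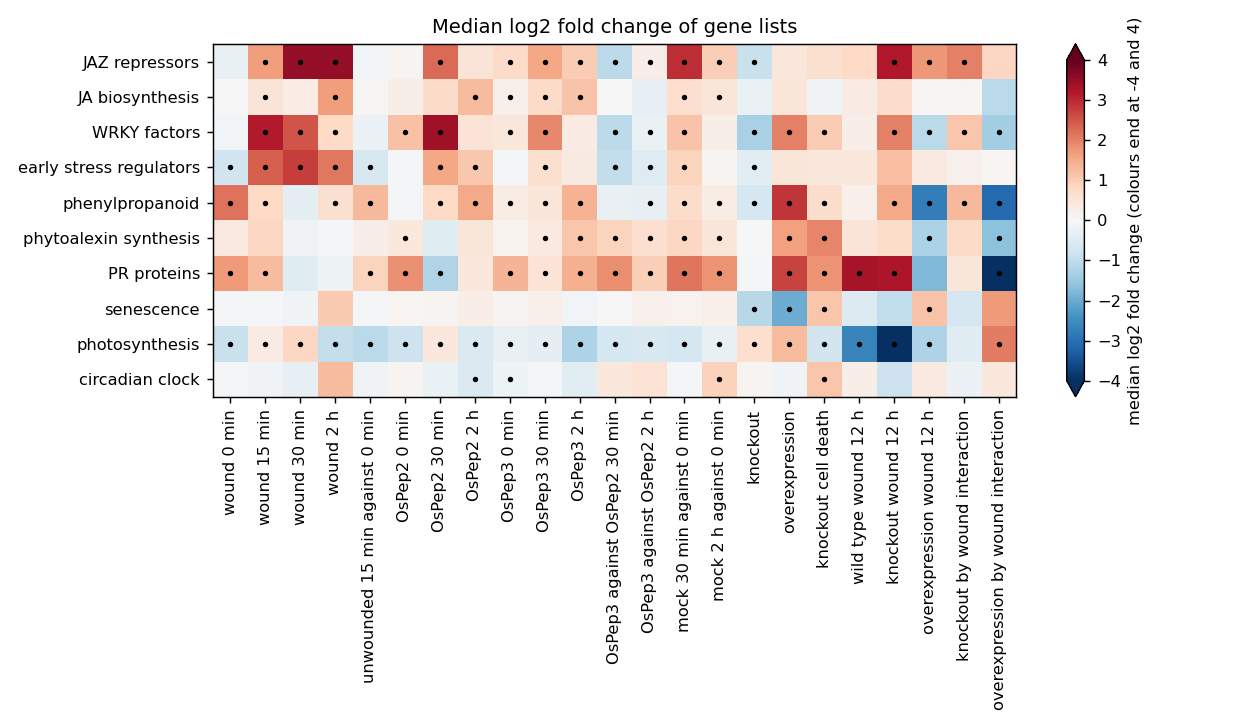
Median log2 fold change of 10 gene lists (vertical axis) in the 23 comparisons (horizontal axis), as colour, with a dot where camera at the preset correlation passed after Benjamini-Hochberg adjustment. JAZ repressors reached 3.53 at 30 min and 2 h after wounding, and photosynthesis genes fell by 4.56 in wounded knockout leaves at 12 h.

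Responses were then compared across experiments that share no library. Of 11805 genes tested in both courses, 660 rose both at 30 min after wounding and at 30 min with OsPep2, where independent lists would share 147.7, and 229 fell in both against 44.5 (405 and 622 on FPKM as deposited). The log2 fold changes correlated at r = 0.51 across genes, which are not independent replicates. With OsPep3 at 30 min the shared rises were 229 against 38.8, and r was 0.3. At 2 h, wounding shared 430 rises with OsPep2 against 145.3 (r = 0.35) and 332 with OsPep3 against 85.5 (r = 0.45). Wounding at 12 h in wild type shared 547 rises with wounding at 2 h against 246.1 and 385 falls against 123 (772 and 295 on FPKM as deposited), and 258 genes moved in opposite directions. OsPep2 and OsPep3 shared 425 rises at 30 min against 56.1 and 816 at 2 h against 107.5. Their fold changes correlated at 0.69 and 0.82, where unchanged groups simulated against the same mock libraries gave 0.5, and their covariances of 0.392 and 0.566 stood above the simulated 0.033. The knockout and overexpression lines shared 206 rises against 54.9 and 107 falls against 19.1, while 121 genes moved in opposite directions, with a correlation of 0.24 against a simulated 0.5 and a covariance of 0.126 against 0.04. The 2 control libraries were not split between the comparisons, which would leave 1 library to each, so part of these excesses may come from the shared controls.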

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

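The tests of a clock shift by overexpression, of a later rise of PDC2, the test on the unwounded leaves of 0 min, and list tests on matched members were chosen only after the result was seen.

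Each value in this paragraph and the next comes from a tested difference between groups, by limma contrast or camera. For the change with wounding in knockout against wild type, 3981 genes differed, with medians of 2.01 for JAZ repressors, 1.31 for phenylpropanoid genes, 2.44 for vascular markers and 1.12 for WRKY factors. These 4 list calls were lost with an estimated correlation (camera, Benjamini-Hochberg adjusted p = 0.0681, 0.103, 0.108 and 0.0954). Single genes differed by 3.98 (JAZ8), 3.95 (JAZ10), 3.92 (JAZ13), 3.3 (CAD2) and -3.18 (PORA) on the log2 scale. For overexpression against wild type, 4581 genes differed, with medians of -3.11 for phenylpropanoid genes, 2.06 for photosynthesis, -1.64 for phytoalexin genes, -5.19 for PR proteins and -1.36 for WRKY factors. These 5 list calls were lost as well (adjusted p = 0.12, 0.146, 0.0669, 0.0658 and 0.0831 with an estimated correlation). The photosynthesis median turned to -0.79 with matched members only, which are CAB1R, CAB2R, PORA and PORB. Single genes differed by -8.28 (WRKY62), -7.03 (WRKY76), 6.96 (CAB1R), 6.62 (PRR95) and -3.67 (CAD2). Differences already present in unwounded leaves, as for JAZ10, WRKY62 and WRKY76, are part of these interaction values.

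OsPep3 and OsPep2 differed in 2314 genes at 30 min, with medians of -1 for early stress regulators, -1.38 for epidermis and wax markers, -1.06 for JAZ repressors, -1.33 for peptide signalling, -0.71 for photosynthesis, 0.9 for phytoalexin genes, 1.87 for PR proteins and -1.06 for WRKY factors. With an estimated correlation the calls of epidermis and wax markers and of peptide signalling were lost (adjusted p = 0.071 and 0.0507), and under quantile normalization those of JAZ repressors and photosynthesis. Single genes differed by -2.7 (MPK3), -2.5 (JAZ9), -2.45 (WRKY24), -1.63 (JAZ13) and -1.57 (WRKY71). At 2 h they differed in 682 genes, with medians of -0.52 for early stress regulators, 0.27 for JAZ repressors, -0.29 for peptide signalling, -0.33 for phenylpropanoid genes, -0.62 for photosynthesis, 0.67 for phytoalexin genes, 0.96 for PR proteins and -0.26 for WRKY factors. With an estimated correlation only the calls of photosynthesis, phytoalexin genes and PR proteins held at 2 h, and the median of early stress regulators turned to 0.06 with matched members. Single genes differed by -2.23 (DREB1A), 1.31 (CYP76M8), 1.21 (JAZ8) and 1.17 (CYP71Z7).

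Wounded overexpression leaves lacked most 12 h changes of wounded wild type and knockout leaves, as 525 of 2287 genes called alike in those genotypes were called the same way and 256 the opposite way. Exchanged labels within the overexpression line, taken alone, were argued against, since its unwounded libraries showed a share of 0.06 of the wild type change. Together with collection at another time of day such an exchange stays open, as hours and wounding are not separated in these genes. A shift of the clock by overexpression stays open. In unwounded overexpression leaves 0 of 6 clock genes passed both thresholds by limma, but 2 had an unadjusted p under 0.05 and the same 2 an adjusted p under 0.05, PRR95 with a log2 fold change of -0.73 and PRR1 with -0.64. Collection at another time of day could not be excluded either, as the median share of the wild type change kept was 0.32 over 699 genes also called at 2 h after wounding and 0.1 over 836 genes called at no earlier wound time. The latter met the bound set for this cause and the former lay between the bounds. A biological explanation, such as a weaker wound response of the overexpression line, may act as well, untested without unwounded leaves of 12 h.

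PDC2 of the low oxygen list was higher in OsPep2 strips at 0 min, with a log2 fold change of 2.88. No other member was tested there by limma, and the list call was lost (camera, Benjamini-Hochberg adjusted p = 0.06 with an estimated correlation). ADH2 was at 39.4 and 35.5 scaled FPKM against 0.0884 and 0.205 in mock libraries. HB1 was at 177 in the 1 OsPep2 library with a value, against 18 and 19.7 in mock libraries and 68.9 and 61.3 with OsPep3. PDC1 was at 0.311 in the 1 OsPep2 library with a value, and RAMY3D was listed at 0 in both. A rise that builds up after the peptide was argued against for PDC2, since its net change at 30 min was -1.16 on the log2 scale (SE 0.13). PDC2 was picked for its difference at 0 min, which the net change subtracts, so the choice favoured this outcome. ADH2 and HB1, not tested, had net changes of 0.02 and -0.25. Scaling was argued against for PDC2, which kept a log2 change of at least 2.87 under both other scalings. Different conditions of the strips before the peptide may account for the difference, which was not tested.

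Unwounded leaves of 0 min and just wounded leaves differed in 941 genes. Of them, 65 (6.91%) were called alike against unwounded leaves of 15 min. Only 121 genes were called there in all, which caps the shared calls, so that share alone cannot weigh a response to the wound within minutes. Between unwounded leaves of 15 min and the same leaves of 0 min, 530 of the 941 were called alike. These 530 argue against the wound as the whole cause and leave it open as part of it. Sequencing depth is unknown and stays open. The implied fragments, a measure of relative precision, averaged 3920000 in unwounded leaves of 0 min and 4310000 in just wounded leaves. They averaged 6740000 in unwounded leaves of 15 min, from which just wounded leaves differed in 121 genes. These values argue against unequal precision as the cause of the 941 differences. A difference in collection or growth of the unwounded leaves of 0 min may remain, which was not tested.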

How the results depend on the processing

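The alternatives with matched members, exchanged controls, values net of 0 min, a looser join, a block on the replicate mark and genotype fits without wounded transgenic groups were chosen only after the data were seen. Of values under other settings, named genes kept direction and call in 1775, lost the call in 62 and turned in 10, and with a library left out in 1304, 32 and 0. Lists kept theirs in 995, lost the call in 145 and turned in 13. Leaving out a library moved no count of genes by more than 1.5 times. Counts that moved by more were unwounded 15 min against 0 min on FPKM as deposited (1140 from 706), wound 0 min against unwounded leaves of 15 min (121 from 941), and at a pseudocount of 0.1 OsPep3 at 0 min (411 from 218), OsPep3 against OsPep2 at 2 h (1142 from 682), mock at 2 h (735 from 438) and the overlap of knockout and overexpression (508 from 313). List calls fell from 138 to 63 with an estimated correlation and to 81 with matched members. Medians that turned were photosynthesis with OsPep2 at 30 min (0.43, but -0.08 as deposited and -0.12 under quantile normalization) and, with matched members only, PR proteins in unwounded leaves (-0.38), early stress regulators in OsPep3 against OsPep2 at 2 h (0.06), photosynthesis in mock at 2 h (0.02) and photosynthesis in the overexpression interaction (-0.79). With matched members, the PR value is that of Cht1 alone, and the photosynthesis medians cover only CAB1R, CAB2R, PORA and PORB. Against unwounded leaves of 15 min alone, medians turned just after wounding for early stress regulators (0.12) and photosynthesis (0.21) and at 2 h for phenylpropanoid genes (-0.16), and just after wounding JAZ10 (0.37), JAZ13 (1.15), PORA (0.89), CAB2R (0.56) and WRKY76 (0.93) turned. Against those of 0 min alone, photosynthesis (-0.75) and PORA (-0.7) turned at 15 min. Net of 0 min, LOX9 (-0.71 at 30 min and -0.67 at 2 h), PDC2 (-1.16 and -0.8) and photosynthesis at 2 h (0.41) turned with OsPep2, and PR proteins at 30 min (-0.91) with OsPep3. At 2 h the latter's median shrank to 0.05 from 1.41, where camera's direction was down. Where members, control or baseline were changed, a turn shows that the result depends on that choice. Why it does was not tested, nor was the cause of the other turns. FPKM as deposited put the median of all genes at -0.43 from -0.04 (OsPep2 30 min), 0.42 from 0.08 (wild type 12 h) and 0.41 from 0 (unwounded). That setting also gave -0.4 from -0.05 (wound 30 min), 0.39 from 0.01 (OsPep3 against OsPep2 30 min) and -0.37 from 0 (knockout interaction). On it, higher and lower calls were 818 and 185 (wound 0 min), 1013 and 127 (unwounded), 468 and 264 (OsPep3 against OsPep2 2 h), 1049 and 861 (overexpression), 1217 and 594 (cell death) and 1597 and 915 (overexpression 12 h). At a pseudocount of 0.1 they were 1668 and 1142 (wound 30 min) and 1633 and 1145 (overexpression), and net of 0 min 460 and 182 (OsPep3 30 min). Libraries with the same replicate mark in the titles did not deviate together from their group means, with a correlation across genes over 0.1 in 1 of 72 pairs of groups (-0.09 to 0.11). With this mark as a replicate block the counts of genes were 0.986 to 1.01 times those without it over the 23 comparisons, such as 696 from 706 between the unwounded times, and no named gene or list changed call or direction. Depth may limit genes near 1 FPKM, which was not tested. Changes of 2-fold were called in 32 to 58% of simulated genes, whose means were well above 1 FPKM.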

Other observations

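The tests in this part were fixed before the data were examined, and the genes named were picked from the fixed lists after their values were seen.

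The root marker LSI2 was listed at 0 in all 44 libraries, and LSI1 stood at 22.3 ± 1.7 scaled FPKM (SD, n = 2) in unwounded wild type and 17.4 ± 0.8 in unwounded knockout leaves. The root marker list, with 1 member tested, passed camera in none of the 23 comparisons. The seed marker GLUA1, a storage protein gene, was at 2.89 and 3.05 in the libraries of 30 min after wounding and at most 1.72 in the others, and was not tested, being without a value in some libraries. Markers of dividing cells passed camera in none of the 23 comparisons, although PCNA, a DNA replication gene, was at 1.7 ± 0.11 with OsPep2 at 2 h against 5.11 ± 0.81 in mock.

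The starch degradation gene RAMY3D, fixed as a low oxygen gene, rose at 30 min after wounding to 11 ± 0.13 scaled FPKM (SD, n = 2) from 0.019 ± 0.022 (SD, n = 4), a log2 fold change of 3.56 (SE 0.14, limma with Benjamini-Hochberg adjustment, adjusted p = 9.2e-08). It was at 2.98 ± 0.74 at 2 h. In OsPep2 strips at 2 h the chlorophyll breakdown gene SGR was at 33.3 ± 0.71 against 10.5 ± 0.63, and the chlorophyll synthesis gene PORB fell to 83.3 ± 1.1 from 265 ± 3.6.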
